A study of Mus musculus with 2 samples.

How the data were processed

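The series profiled splenic natural killer (NK) cells of wild-type mice with droplet-based single-cell RNA sequencing. Per the labels' protocols, NK cells were isolated from dissociated spleens by negative selection, in which antibodies hold back erythroid cells, macrophages, granulocytes, dendritic cells and the B and T lineages. Libraries were made with the 10x Genomics 3′ v3.1 chemistry, per the labels' protocols, and cells of different mice were combined by lipid tagging, per the series' design text. Both of the 2 samples in the labels belong to 1 group; 1 of them has the matrix analysed here, and the other was not analysed here. Whether the tags include cells of that other sample is not known. The matrix holds counts of unique molecular identifiers (UMIs) for 32285 genes and 3 lipid tags in 16384 barcodes, as the authors deposited it. It was written by Cell Ranger 7.0.0, per the file headers, and the submitters' processing notes name Cell Ranger, Seurat and the mouse build mm10. The annotation used for counting, and whether reads in introns were counted, are not given in the sources used here. Levels are given as CPM, the UMIs of a gene scaled to the gene UMIs of the same cells. No normalized values were used: everything below was computed from the deposited counts.

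The labels do not say which tag belongs to which mouse, or that a tag stands for 1 mouse. The 3 tags were therefore treated as 3 replicates of 1 library, called tag 1, tag 2 and tag 3. In the main fit, p-values set the difference between classes only against its variation from tag to tag, which may be technical. The spread of each gene was estimated with information shared between genes. A very small p-value therefore does not rest on the 3 tags of that gene alone. All cells share 1 library and 1 batch label, so no difference between batches could be examined.

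Barcodes with 500 to 6000 detected genes and at most 10% mitochondrial UMIs were kept, which left 15742 and removed 642. Scrublet was to remove doublets at an expected rate of 0.8% per 1000 barcodes, and called 0 doublets at an expected 12.6%, so it had not worked on this matrix. A threshold per tag, set by Otsu's method on log10 of the tag count plus 1, was used in its place, and only barcodes above exactly 1 threshold were analysed. The thresholds were 140 counts for tag 1, 196 for tag 2 and 138 for tag 3. This step was chosen after the data were examined. The planned set, with all barcodes that passed the filter, is kept as an alternative. There the barcodes were clustered and named anew, and each took its highest tag relative to the threshold. The NK-like class itself therefore differs in that alternative, not only by the added barcodes. In all, 3540 barcodes carried several tags, 508 carried none and 11694 were analysed. From the tag proportions, 66.5% of doublets should carry 2 tags, so about 1781 doublets of 2 cells with the same tag are expected among the analysed cells, which is 15.2% of them.

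Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (Python 3.11.15, scikit-learn 1.9.0, seed 1) on 2000 highly variable genes, 30 principal components and 15 neighbours at a Leiden resolution of 1.0. The genes of the potassium channel, glycolysis, oxidative phosphorylation, mitochondrial, ribosomal and cell cycle lists were left out of the clustering. Clusters were named from markers of 16 cell types fixed before the data were examined. A type's score was the mean over its markers of the share of cells with a UMI, relative to the highest share in any cluster. A name needed a score of at least 0.5, at least 3 markers in 10% or more of the cells, and no lead of another type's markers among the 10 genes with the highest fold (20 CPM added). Clusters with a median UMI total below the library's divided by 3 and no own marker among those 10 genes stayed unnamed. Cluster 5, whose best score was NK, was only just below that bound, with a median of 1394 against 4201 UMIs in the library. Clusters 7 and 10, with NK as best score too, stayed unnamed because T cell markers but no NK marker stood among those 10 genes. In cluster 7 that was Cd28 alone, which is also on the fixed immature NK list, and in cluster 10 it was Cd3d and Cd3g. The score and its thresholds were set after clusters had been looked at, over several rounds. They keep 1778 cells whose best score was NK out of the NK-like class, so the main values were also computed with those cells.

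For maturation classes, each NK-like cell was thinned to 2500 UMIs, the 10th percentile of their totals, rounded down, which left out 621 shallower cells. Cells were then classed by UMIs of Cd27 and Itgam (CD11b) as Cd27-only, Itgam-only, both or neither. Unthinned counts were summed per tag and class and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test with TMM scaling, edgeR's expression filter, tag as a block and Benjamini-Hochberg adjustment at 0.05. The design fixed in advance planned this fit, with the tag as a block, for the case that tags separate enough animals. The labels do not say that they do. The deviations of sums with the same tag correlated at 0.44, 0.23 and 0.24 over 4858 genes, each above the minimum of 0.1 for pairing. Sums held 1213954 to 1813158 UMIs in Cd27-only and 3040588 to 4289628 in Itgam-only cells. Tested on simulated counts for this comparison (9701 genes, 200 of them drawn to change), the procedure recovered 81.8% of 99 changes of 2-fold and 100% of 100 changes of 4-fold, with 12 false calls or 6.22% of all calls. The simulated genes followed the average trend of the spread and a tag effect shared by both classes, as the fit assumes. That rate therefore does not cover genes that vary more. The 17 gene lists were fixed before the data were examined. Of these, 16 with 5 or more tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The latter test draws on the few residual degrees of freedom that 6 sums with a tag block leave. It had little power, so a list that did not pass it is not thereby shown to be unchanged. The same lists were tested with fry, without adjustment. Neither camera nor fry was named in the design fixed in advance.

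Single values have exact Poisson intervals for sums and exact Clopper-Pearson intervals for shares, at 95%, which cover counting error only; a count of 0 allows up to 3 counts. Genes were named by a rule fixed in advance. It took the 4 KATP channel genes, the 6 channel genes with most UMIs, and the 12 highest and 12 lowest log2 ratios of summed UMIs (0.5 UMIs added) among genes with at least 50 CPM in either class. Cd27, Itgam, mitochondrial and ribosomal protein genes and unnamed gene models were left out of that ranking. The rule added up to 4 members of each list with the largest ratio among those with at least 20 CPM, and up to 3 markers per class. Coordinates come from GENCODE M21 on mm10 by gene identifier, which matched 32158 of the genes. The 78 features that share a symbol were kept apart by identifier.

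Alternatives fixed in advance, each for some of the results, were Leiden resolutions of 0.5 and 2.0, cell filters of 200 genes with 20% and 1000 genes with 5% mitochondrial UMIs, and all barcodes in place of single-tag ones. Others were NK-like cells by single-cell markers, Ncr1-positive cells, means over cells, each tag alone, classes without thinning or with at least 2 UMIs, and classes from clusters. Further ones left out cycling cells, ribosomal and mitochondrial genes or the deepest 10% of cells, or lowered the naming minimum to 10 CPM. Leaving out each tag, the fit without the block, DESeq2 1.42.0, RLE scaling, no expression filter, the wider NK class and the removal of cells near several-tag barcodes were chosen after the data were examined. So were several uses of the alternatives above for further results. These were both resolutions for the Kcnj8 level, the 200-gene filter for its level and rank, and kept doublets for the gene comparison. For the Kcnj8 fold they were at least 2 UMIs and the runs without cycling cells, ribosomal and mitochondrial genes or the deepest cells.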

Results

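The data are 1 single-cell library of NK-selected splenocytes from wild-type mice, in which 3 lipid tags mark cells pooled for the run. The analysed set held 11694 single-tag cells, of which 3599 carried tag 1, 4210 tag 2 and 3885 tag 3. Their total gene UMIs were 18565224, 23060242 and 22404924, with medians of 4028, 4432.5 and 4122 UMIs per cell. The series concerns Kir6.1, the pore-forming subunit of an ATP-sensitive potassium (KATP) channel encoded by Kcnj8, and its part in NK cell development. All cells were wild type, so the comparisons are between cell classes within the library, and no effect of losing the channel is measured.

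NK-like cells were the main class, and the selection also left B cell-like, ILC1-like, dendritic cell-like and other classes in small shares. NK-like cells made up 61.4% ± 4.53 of a tag's cells (SD, n = 3), or 7187 of 11694 cells (61.5%, 60.6 to 62.3%). Gzma, a granule protease, had a UMI in 99.4% of them, Klre1 in 98.2% and Klrb1c, which encodes NK1.1, in 97.3%. B cell-like cells, with Ebf1, Cd79a and Ighm as the most widely seen markers, made up 6.15% ± 3.64, and ILC1-like cells, with Il7r, Rora and Tmem176b, 4.29% ± 1.32. Conventional dendritic cell-like cells, with Cd74, H2-Aa and Flt3, made up 3.34% ± 0.588.

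Erythroid-like cells (Car2, Car1, Klf1) accounted for 1.99% ± 1.02 and T cell-like cells (Cd3d, Cd3g, Cd3e) for 1.31% ± 0.827. Mural or fibroblast-like cells (Col1a2, Dcn, Col3a1) ranged from 0.278% of tag 1 to 2.40% of tag 2. The platelet or megakaryocyte-like class (Pf4, Ppbp, Gp9) ranged from 0.333% of tag 1 to 1.5% of tag 2. Monocyte or macrophage-like cells (Lyz2, Csf1r, Ms4a6c), plasma cell-like cells (Jchain, Xbp1, Mzb1), progenitor-like cells (Meis1, Kit, Cd34) and neutrophil-like cells (S100a8, S100a9, Csf3r) each stayed below 0.7% on average. A further 17.4% ± 2.82 of cells stayed unnamed. Cells of unnamed clusters whose best marker score was NK made up 16.7% of tag 1, 16.4% of tag 2 and 12.5% of tag 3. Counting them as NK-like gave a share of 76.7%. The shares describe what passed a negative selection and the tag threshold, not the spleen.

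**Figure D1:**
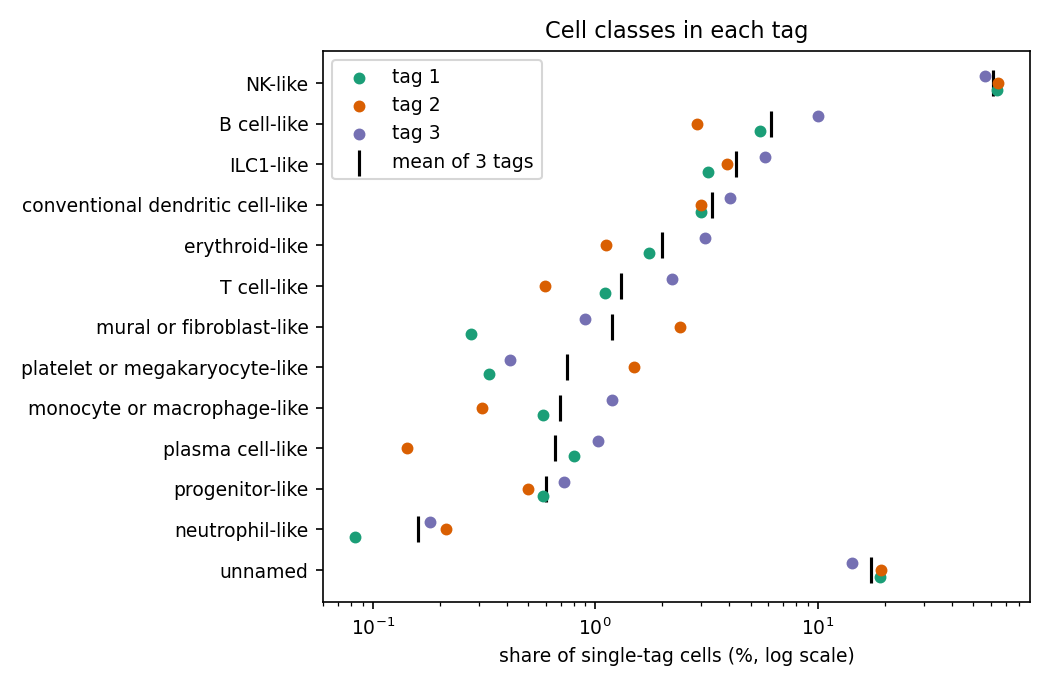
Share of single-tag cells in each class (x axis, percent, log scale) for each of the 3 tags (coloured points), with the mean of the tags as a black bar. NK-like cells lie at 63.8%, 64.3% and 56.2% in tags 1, 2 and 3, far above every other named class.

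Of the 4 genes that encode KATP channel subunits, Kcnj8 was the one clearly detected in NK-like cells. Kcnj8 stood at 53.8 ± 6.12 CPM (SD, n = 3), or 1796 UMIs in 33794435 (53.1 CPM, 50.7 to 55.7). Kcnj11, which encodes the pore subunit Kir6.2, had 3 UMIs (0.0888 CPM, 0.0183 to 0.259). Abcc9, which encodes the regulatory subunit SUR2, had 1 UMI (0.0296 CPM, 0.000749 to 0.165). Abcc8, which encodes SUR1, had 0 UMIs (exact interval up to 0.109 CPM). The floor of 3 counts lay at 0.0888 CPM. At this depth the 3 other subunits were therefore at or under the floor in NK-like cells. Abcc9 had 6 UMIs in mural or fibroblast-like cells (4.86 CPM, 1.78 to 10.6), so its transcript could be counted in this library.

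A Kcnj8 UMI was seen in 1344 of 7187 NK-like cells (18.7%, 17.8 to 19.6%) at a median depth of 3904 UMIs. In B cell-like cells, a class taken to lack the gene, the share was 1.41% (0.677 to 2.57%) at a median of 3901.5 UMIs. ILC1-like cells had one in 10.5% (7.98 to 13.5%) at a median of 5209 UMIs and stood at 22.4 CPM (17.3 to 28.5). T cell-like cells stood at 7.27 CPM (2.92 to 15). In mm10, Kcnj8 (ENSMUSG00000030247) lies on chromosome 6 from 142564837 to 142571614 on the minus strand and overlaps 0 other annotated genes. Abcc9 (ENSMUSG00000030249) lies on the same chromosome from 142587862 to 142702315. Kcnj11 (ENSMUSG00000096146) lies on chromosome 7 from 46093953 to 46100764, and Abcc8 (ENSMUSG00000040136) on the same chromosome from 46104523 to 46180033.

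Kcnj8 ranked at place 5 among the 101 genes compared, which were all features with a Kcn symbol together with Abcc8 and Abcc9. Kcnq5, a voltage-gated channel gene, led with 806 ± 18.6 CPM (SD, n = 3). It was followed by the antisense transcript Kcnq1ot1 at 123.2 ± 6.26, Kcnip3 at 95 ± 8.17 and Kcnab2 at 86.6 ± 8.40. None of these 3 encodes a pore: Kcnip3 encodes a channel-interacting protein and Kcnab2 an auxiliary beta subunit. Kcnk10, a 2-pore-domain channel gene, came next below Kcnj8 at 13.3 ± 3.53. In all, 8 of the genes reached 10 CPM, 43 had at least 3 UMIs and 32 had 0. Kcnq5 spans 563.54 kb on chromosome 1 (21398403 to 21961942) and overlaps 4 annotated gene models, so reads may be shared among them; Kcnj8 spans 6.78 kb. The gap of Kcnq5 to Kcnj8 was far larger than the spread between tags, and no test between genes was made.

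**Figure D2:**
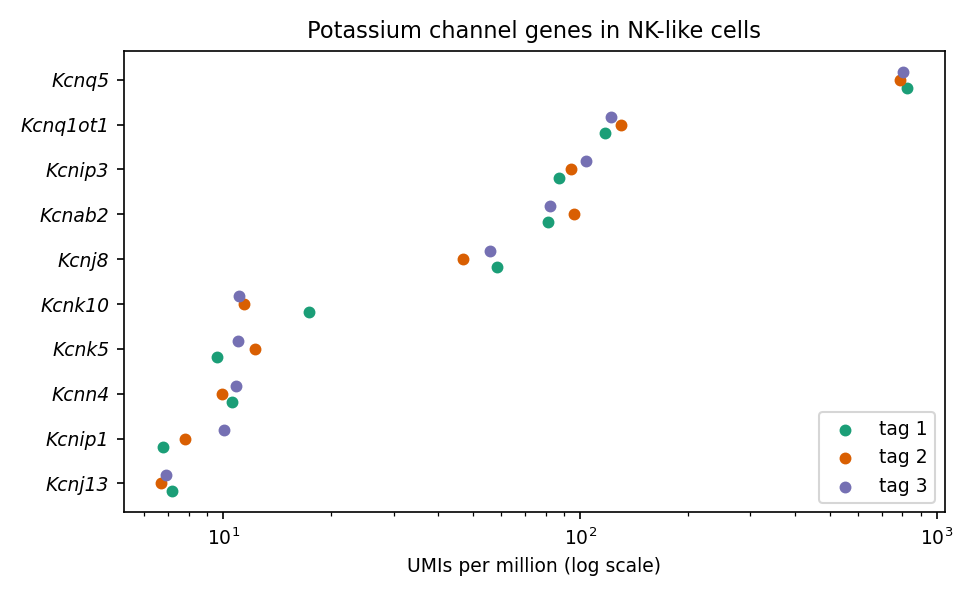
CPM (x axis, log scale) of the 10 potassium channel genes with most UMIs in NK-like cells, one point per tag. Kcnq5 lies near 806, and Kcnj8 lies between 46.9 and 58.6, above Kcnk10 and all genes below it.

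To ask how Kcnj8 and other genes differ with maturation, NK-like cells were divided by Cd27 and Itgam, whose products mark early and late stages of mouse NK development. Of the 6566 cells deep enough, 760 were Cd27-only, 2414 Itgam-only, 378 had both and 3014 neither. These were 11.6% ± 0.398, 36.8% ± 0.624, 5.73% ± 0.269 and 45.9% ± 0.258 of a tag's cells (SD, n = 3). The division rests on few molecules: 82.4% of Cd27-only cells had exactly 1 Cd27 UMI and 65.2% of Itgam-only cells exactly 1 Itgam UMI. Cluster 1 held 61.3% of Cd27-only cells, and cluster 2 held 31.0% and cluster 1 22% of Itgam-only cells. Median depths were 4991 UMIs in Cd27-only and 3803 in Itgam-only cells before thinning.

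Kcnj8 was 2.97-fold lower in Cd27-only than in Itgam-only cells. It stood at 24.1 ± 7.36 CPM in Cd27-only and 72.2 ± 7.31 in Itgam-only cells (SD, n = 3), a log2 fold of -1.57 (SE 0.15, adjusted p = 7.3e-09 by edgeR's quasi-likelihood test, lower in 3 of 3 tags). Cells with both UMIs stood at 32.1 ± 11 and cells with neither at 45.2 ± 5.01. Between cells with both and Itgam-only cells the log2 fold was -1.08 (SE 0.19, edgeR adjusted p = 4.0e-04). Between Cd27-only cells and cells with both it was -0.50 (SE 0.25, edgeR adjusted p = 0.50), which did not pass. These 2 fits were chosen after the data were examined. After thinning to 2500 UMIs, 7.56% ± 2.96 of Cd27-only, 9.21% ± 2.97 of cells with both and 16.0% ± 1.24 of Itgam-only cells held a Kcnj8 UMI. B cell-like cells held one in 0.954% (0.351 to 2.06%) at the same depth.

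Across NK-like clusters, which were made without channel genes, Kcnj8 was highest in 2 clusters with high mature genes. Clusters 2 and 4, in which the median of the mature list lay above and that of the immature list below the other NK-like cells, stood at 135 CPM (126 to 144) and 99.0 (90.2 to 108). Cluster 9, also of that kind, stood at 83.7 in tag 1, which held 344 of its 473 cells, 58.9 in tag 2 and 20.2 in tag 3 (54.3 ± 32; SD, n = 3). In tag 3 it was thus below cluster 3, which stood at 32.7 there. Cluster 1, of the opposite kind, stood at 13.3 (11.5 to 15.3), and the cycling cluster 16 at 3.93 (1.58 to 8.09). The remaining NK-like cluster, 3, stood at 34.1 (29.1 to 39.6). Tested between the immature and mature clusters, the log2 fold was -3.11 (SE 0.10, edgeR adjusted p = 4.0e-21). These clusters were formed and staged from other genes of the same cells, so this fold is no independent check. With the barcodes of several or no tags kept in, the log2 fold between Cd27-only and Itgam-only cells fell to -0.86 (SE 0.14, edgeR adjusted p = 3.7e-04). That setting also formed and named the clusters anew, so the fall cannot be assigned to the added barcodes alone. Over all alternatives run, by edgeR or DESeq2, the adjusted p ran from 4.0e-26 to 3.7e-04.

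**Figure D3:**
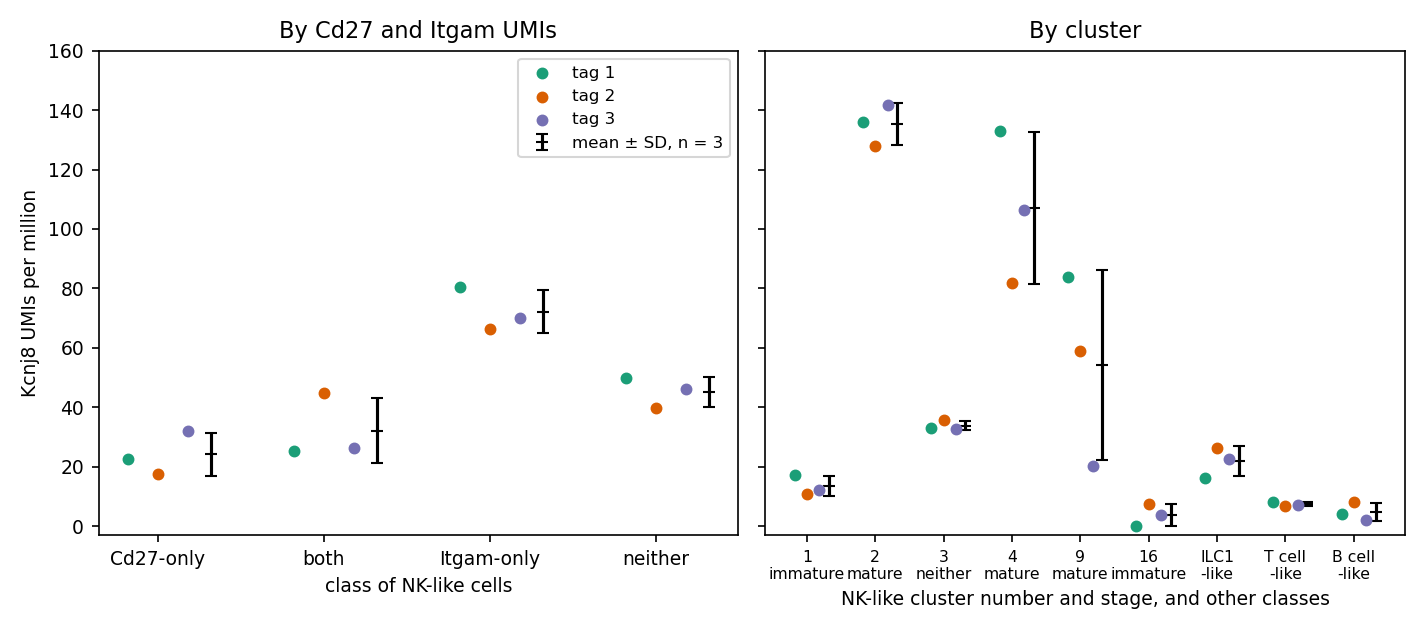
Kcnj8 CPM (y axis) in the classes by Cd27 and Itgam (left) and in NK-like clusters and 3 other classes (right), one coloured point per tag with the mean ± SD of the 3 tags in black. Itgam-only cells average 72.2 and Cd27-only cells 24.1, and clusters 2 and 4 lie highest on the right.

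Beyond Kcnj8, 12 of 14 fixed immature NK genes were higher and 14 of 15 fixed mature NK genes lower in Cd27-only cells. As lists, neither passed with an estimated correlation (adjusted p = 0.093 and 0.094). Cd27 and Itgam define the classes and were left among the tested genes, so their own differences were built in. By edgeR's quasi-likelihood test 938 of 9856 genes passed an adjusted p of 0.05, of which 569 were higher and 369 lower in Cd27-only cells. The counts were 336 and 146 without the tag block, 212 and 86 by DESeq2, and 240 and 148 with at least 2 UMIs of the gate gene. They were 1121 and 803 with classes from unthinned counts, and 2062 and 1681 between clusters. The clusters were formed from the expression of these same cells and staged by the fixed immature and mature lists. Many calls between them were therefore built in, and such calls, here and below, are no independent support. Lower genes numbered 566 with all clusters scored NK, 233 with barcodes of several or no tags kept in, and 226 or 191 without tag 1 or tag 2. Among the genes named by ratio, Emb, which encodes embigin, was 3.13-fold higher (638 ± 220 against 207 ± 52.7 CPM; SD, n = 3). Ltb, which encodes lymphotoxin beta, was 2.90-fold higher (137 ± 10.7 against 49.0 ± 6.72). Plxnc1 was 2.82-fold, Kbtbd11 2.54-fold, and the transcription factor genes Myb and Tcf7 2.48-fold and 2.35-fold higher. Cmtm7, Rftn1, Nrgn and the adhesion molecule gene Crtam were 2.22-fold to 2.34-fold higher. All of these were higher in 3 of 3 tags, with edgeR adjusted p of at most 1.5e-07. With at least 2 UMIs of the gate gene Nrgn and Crtam did not pass (log2 folds of 0.77 and 0.87), nor did Crtam with barcodes of several or no tags kept in (0.56). Hist1h1b and Top2a, both genes of dividing cells, were 2.63-fold and 2.70-fold higher (edgeR adjusted p = 7.3e-04 for each), but in 2 of 3 tags. Without tag 3 their log2 folds were 0.56 and 0.83 and neither passed; without tag 2 they were 2.01 and 2.40. Neither passed by DESeq2, Hist1h1b did not pass without the tag block and turned to -0.13 without the deepest cells and to -1.01 without cells holding Mki67 or Top2a, and Top2a did not pass without the deepest cells (0.70).

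On the lower side, Cx3cr1, the fractalkine receptor, was 5.95-fold lower (10.1 ± 5.24 against 64.5 ± 15.8 CPM; SD, n = 3). Cdc20b was 3.44-fold lower, Entpd1, which encodes the ectonucleotidase CD39, 3.26-fold, and Klrg1, an inhibitory receptor of late NK cells, 3.08-fold. Ly6c2 was 2.90-fold and the protease gene Cma1 2.68-fold lower. Gzmb, which encodes granzyme B, fell from 456 ± 8.05 in Itgam-only to 196 ± 7.91 in Cd27-only cells, a 2.24-fold difference. Fgl2, Klra9, S100a4 and S1pr5, an egress receptor gene, were 1.91-fold to 2.02-fold lower. All of these were lower in 3 of 3 tags, with edgeR adjusted p of at most 5.3e-06. With barcodes of several or no tags kept in, S100a4 turned direction (log2 fold of 0.19).

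**Figure D4:**
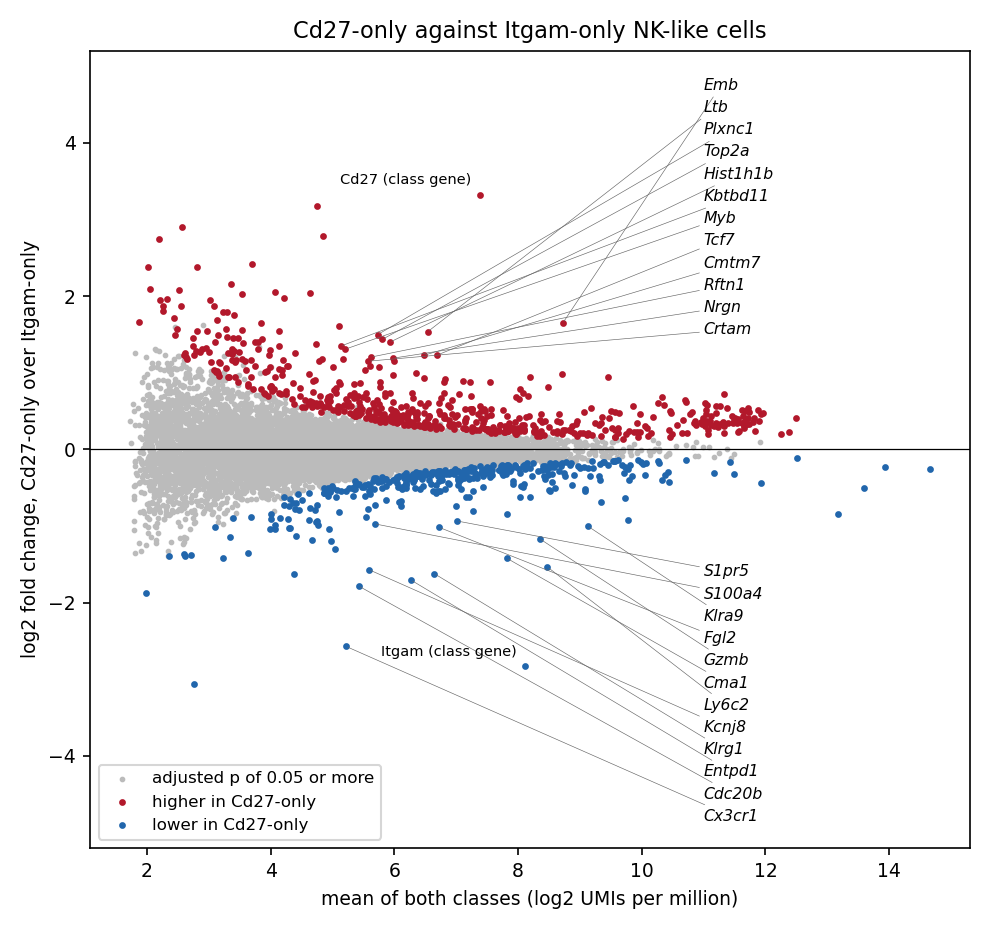
Log2 fold change of each tested gene between Cd27-only and Itgam-only NK-like cells (y axis) against its mean of both classes (x axis, log2 CPM), red where higher and blue where lower at an adjusted p below 0.05. The 24 genes named by ratio carry labels, as do Cd27 and Itgam, which define the classes; Kcnj8 lies at -1.57.

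Of 14 tested immature NK genes 12 rose and 0 fell in Cd27-only cells (13 and 0 adjusted over the list alone), among them Emb, Ltb, Tcf7 and Cxcr3, a chemokine receptor gene at a log2 fold of 1.08. Of 15 mature NK genes 14 fell and 0 rose (14 fell and 1 rose adjusted over the list alone), led by Cx3cr1, Klrg1, Ly6c2 and Cma1. Camera with the preset correlation called both (adjusted p = 3.5e-60 and 2.1e-76), and with an estimated correlation neither passed (adjusted p = 0.093 and 0.094). None of the 16 lists passed with an estimated correlation, which with so few residual degrees of freedom does not tell against them. By fry the unadjusted p was 0.0012 for the immature and 0.0047 for the mature list. Over the lists the fry p ran from 0.00070 for mitochondrially encoded genes to 0.33 for cytokines and chemokines. Among fixed T cell markers, 3 of 4 tested genes were higher in Cd27-only cells, namely Cd3g, Cd3d and Cd28 (log2 folds of 1.69, 1.17 and 0.92), the first 2 at 13.7 ± 11.7 and 17.8 ± 11.7 CPM there. Cd3g and Cd28 were higher in 3 of 3 tags and Cd3d in 2. These 3 genes, and Kit below, were named after their values were seen. Cd28 is also on the fixed immature NK list. Of the NK markers 6 of 10 were lower, and of the ILC1 markers 1 of 4 was higher and 1 lower. Among markers of the other types, 1 of 1 tested B cell gene, 1 of 3 plasmacytoid dendritic cell genes, 2 of 3 progenitor genes, 1 of 5 erythroid genes and 1 of 1 endothelial gene were higher, and 1 of 1 platelet gene was lower. The progenitor genes were Kit and Myb, which are also on the fixed immature NK and transcription factor lists, respectively. None of the tested conventional dendritic cell, monocyte, plasma cell or other innate lymphoid markers passed, and no neutrophil, basophil or mural marker was high enough to be tested.

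Of 19 cytotoxic granule genes 8 fell and 2 rose in Cd27-only cells (10 and 3 adjusted over the list alone). The list's camera p was 4.2e-12 when adjusted, and with an estimated correlation adjusted p = 0.094. Gzma, the most abundant, was 1.79-fold lower and Prf1, which encodes perforin, 1.55-fold lower, while Gzmm was 2.12-fold higher, which did not pass by DESeq2 (log2 fold of 1.09); Gzmb is given above. Of 10 cytokine and chemokine genes 3 rose and 2 fell (4 and 3 adjusted over the list alone). Ltb and Xcl1 rose, the latter 1.92-fold, and Ccl5 and Ccl4 fell 1.42-fold and 1.27-fold; camera adjusted p was 0.21, and with an estimated correlation adjusted p = 0.66. With all clusters scored NK, Ccl4 turned direction (log2 fold of 0.050), and it did not pass without the tag block (-0.36), with at least 2 UMIs of the gate gene (-0.13) or with unthinned classes (-0.15).

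Trafficking receptors and integrins divided evenly, with 5 of 17 higher and 5 lower in Cd27-only cells (6 and 8 adjusted over the list alone). Camera adjusted p was 0.045, and with an estimated correlation adjusted p = 0.34. Ccr2 was 1.72-fold and Cxcr3 2.11-fold higher, and Cx3cr1 and S1pr5 were lower. Of 37 NK receptor genes 12 fell and 4 rose, both over all genes and adjusted over the list alone. Camera called the list lower (adjusted p = 4.6e-04), and with an estimated correlation adjusted p = 0.13; its median log2 fold was -0.04 and its mean 0.01, of opposite sign. Slamf6 rose 4.10-fold, Crtam 2.22-fold and Cd160 2.00-fold, and Klra9 fell 2.00-fold. The Klra genes form a family of close copies, so reads may be split among them.

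Of 25 transcription factor genes 9 fell and 4 rose in Cd27-only cells (10 and 6 adjusted over the list alone). Myb, Tcf7 and Tox rose, Tox 1.76-fold, and Zeb2, which acts late in NK maturation, fell 1.89-fold from 1156 ± 17.6 to 593 ± 34.9 CPM (SD, n = 3). The list's median was -0.12 and its mean 0.00; camera adjusted p was 0.10, and with an estimated correlation adjusted p = 0.34.

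Of 89 ribosomal protein genes 80 were higher and 0 lower in Cd27-only cells (81 and 0 adjusted over the list alone), with a median of 1.29-fold. Camera with the preset correlation called the list (adjusted p = 4.0e-178), and with an estimated correlation it did not pass (adjusted p = 0.11). Rps20, Rps19, Rplp0 and Rps2 were 1.53-fold to 1.65-fold higher. Of 13 mitochondrially encoded genes 11 rose and 0 fell, over all genes and adjusted over the list alone. By camera the adjusted p was 4.2e-12, and with an estimated correlation adjusted p = 0.11. In this list mt-Co1 and mt-Co3 were 1.27-fold and 1.22-fold higher, mt-Nd4l 1.21-fold and mt-Nd5 1.19-fold; mt-Nd4l did not pass with any of the tags left out (log2 folds of 0.23 to 0.33), and neither it nor mt-Nd5 passed by DESeq2 or with at least 2 UMIs of the gate gene. Further settings that ended the call of mt-Nd4l were no tag block (0.28), Ncr1-positive cells (0.26), no expression filter (0.25), removal of cells near several-tag barcodes (0.28), and barcodes of several or no tags kept in (0.21). Beside these, the median depth of Cd27-only cells was the larger one, as given above.

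Of 87 nuclear oxidative phosphorylation genes 6 rose, 0 fell and 81 did not pass (5 rose adjusted over the list alone). Camera adjusted p was 0.017, and with an estimated correlation adjusted p = 0.51. Cox6a2 rose 3.92-fold from 7.74 ± 2.09 CPM; it is also the fixed plasmacytoid dendritic cell marker that was higher in Cd27-only cells. Atp5g2 rose 1.30-fold, while Ndufaf4 and Ndufaf2 stood at log2 folds of 0.49 and -0.31 and did not pass. Cox6a2 did not pass with barcodes of several or no tags kept in (1.01), nor Atp5g2 with at least 2 UMIs of the gate gene (0.36), and Ndufaf4 passed with all clusters scored NK (0.62). Of 14 glycolysis genes 5 rose and 1 fell, also adjusted over the list alone. By camera the adjusted p was 0.025, and with an estimated correlation adjusted p = 0.38. The glucose transporter gene Slc2a1 rose 1.59-fold, Gpi1 1.35-fold and Pgam1 1.34-fold, and Slc2a3 fell 1.43-fold. Slc2a3 did not pass without tag 1 or tag 2 (log2 folds of -0.37 and -0.44), nor Pgam1 without tag 2 (0.25). None of these 4 genes passed by DESeq2 or with at least 2 UMIs of the gate gene, and Slc2a1, Slc2a3 and Pgam1 did not pass without the tag block. With barcodes of several or no tags kept in Slc2a1 and Slc2a3 did not pass (0.40 and -0.31), nor did Slc2a3 with all clusters scored NK (-0.32).

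Of 19 cell cycle genes 10 rose and 0 fell in Cd27-only cells (16 and 0 adjusted over the list alone). By camera the adjusted p was 5.8e-10, and with an estimated correlation adjusted p = 0.34. Pclaf rose 6.89-fold in 3 of 3 tags, and Mki67, Top2a and Birc5 rose 3.04-fold, 2.70-fold and 2.54-fold in 2 of 3 tags. Without tag 3 Mki67, Top2a and Birc5 did not pass (log2 folds of 1.05, 0.83 and 0.79), nor did Birc5 without tag 1 (0.84); without tag 2 the 3 stood at 2.63, 2.40 and 2.32, and Pclaf at 3.58. By DESeq2 Mki67, Top2a and Birc5 did not pass, nor did Birc5 without the tag block or Mki67 and Top2a without the deepest cells. The list's median log2 fold was 1.00 and varied between tags with an SD of 1.06.

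Of 12 interferon response genes Bst2 alone rose, 1.43-fold (also adjusted over the list alone), and did not pass without tag 1 or tag 2 (log2 folds of 0.54 and 0.45), without the tag block or by DESeq2. Nor did it pass with at least 2 UMIs of the gate gene (0.72), between clusters (0.24), with barcodes of several or no tags kept in (0.30), or without cells near several-tag barcodes (0.50). Ifi213, Ifi208 and Irf7 stood at log2 folds of 0.46, 0.33 and 0.24 and did not pass; without the deepest cells Ifi213 passed (0.63). Of 19 immediate early and heat shock genes 5 rose and 2 fell (7 and 2 adjusted over the list alone). Nr4a1 rose 1.66-fold and Fosb 1.52-fold, Dusp2 fell 1.39-fold, and Egr1 stood at a log2 fold of 0.66 with an edgeR adjusted p of 0.051; without tag 2 it passed, at 0.97. Nr4a1 and Fosb did not pass without the tag block (log2 folds of 0.71 and 0.60), nor Nr4a1 with barcodes of several or no tags kept in (0.29). Of 18 calcium entry and sodium pump genes 0 rose and 2 fell, also adjusted over the list alone: the calcium pump genes Atp2a3, 1.48-fold, and Atp2b4, 1.25-fold, which did not pass without tag 2 or tag 3 (log2 folds of -0.26 and -0.25), without the tag block, by DESeq2, without cells holding Mki67 or Top2a (-0.25) or without cells near several-tag barcodes (-0.34). Orai3 and Stim1 stood at log2 folds of -0.23 and -0.16 and did not pass; Orai3 passed between clusters (-0.38) and Stim1 with unthinned classes (-0.20). Camera adjusted p was 0.20, 0.15 and 0.20 for these 3 lists, and with an estimated correlation adjusted p = 0.38, 0.59 and 0.38.

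Of 12 potassium channel genes tested 3 rose and 1, Kcnj8, fell in Cd27-only cells (5 and 2 adjusted over the list alone). Kcnc1 rose 2.93-fold from 3.63 ± 0.333 CPM, Kcnn4, a calcium-activated channel gene, 1.81-fold from 9.14 ± 2.18, and Kcnq5 1.10-fold; these 3 were named after their values were seen. Kcnq1ot1, Kcnip3 and Kcnab2 stood at log2 folds of 0.24, 0.16 and -0.26 and did not pass (edgeR adjusted p = 0.051, 0.39 and 0.11); without tag 3 Kcnq1ot1 passed, at 0.31. Between clusters these 3 passed, at 0.51, 0.32 and -0.20, and with unthinned classes at 0.31, 0.24 and -0.26. Camera adjusted p was 0.45, and with an estimated correlation adjusted p = 0.58. Kcnj8 was the 1 tested member of the KATP list, and Kcnj11, Abcc8 and Abcc9 were too low to be tested.

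**Figure D5:**
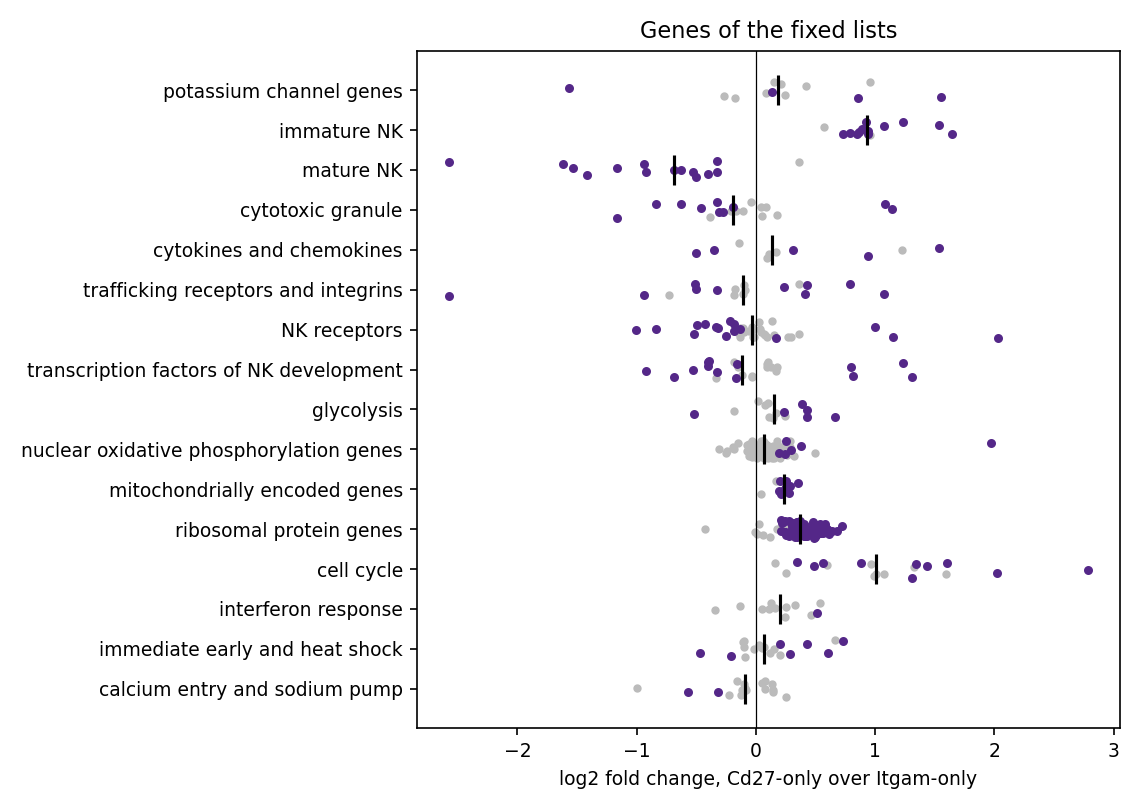
Log2 fold change between Cd27-only and Itgam-only NK-like cells (x axis) of every tested gene of the lists with 5 or more tested members, purple where the adjusted p was below 0.05 and grey elsewhere, with the list median as a black bar. Immature NK genes lie right of 0 and nearly all mature NK genes left of it, and the potassium channel gene farthest left is Kcnj8 at -1.57.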

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

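The count of barcodes with several tags was chosen after the data were examined. Barcodes above the threshold of more than 1 tag were set aside from the main comparisons and entered only the alternatives that keep them in or remove cells near them. They are a signal outside the main measurement. They made up 22.5% of the 15742 barcodes that passed the filter (21.8 to 23.1%, exact binomial interval), with a median of 7945 UMIs against 4201 in single-tag cells. Leaving them in, together with barcodes of no tag, lowered the share called NK-like to 47.3%.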

How the results depend on the processing

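Alternatives chosen after the data were examined were leaving out a tag, the fit without the block, DESeq2, RLE scaling, no filter, the wider NK class, removal of cells near several-tag barcodes, other resolutions for the Kcnj8 level, the 200-gene filter for its level and rank, kept doublets for genes and, for the Kcnj8 fold, at least 2 UMIs and the runs without cycling cells, the deepest cells or ribosomal and mitochondrial genes. Causes of the changes below were not tested, unless stated. The NK-like share (61.5%) moved to 72.5% at a Leiden resolution of 0.5, 77.4% by single-cell markers, 76.7% with all clusters scored NK and 47.3% with doublets kept. The other settings gave 57.1% to 60.6%, and leaving out a tag 59.8% to 64.1%. Kcnj8 in NK-like cells (53.1 CPM) moved to 60.9 at resolution 2.0, 66.5 under the stricter cell filter, 65.9 with doublets kept, 31.6 in all cells, 45.6 in the wider NK class, 60.2 without cells near several-tag barcodes, 69.6 as a mean over cells and 46.9 in tag 2 alone; without a tag it was 50.7 to 57.3. Its rank stayed 5 in all settings run. The Kcnj8 log2 fold kept its sign and passed in all 17 settings, 4 of them fixed in advance, from -3.11 to -0.86; leaving out a tag gave -1.81 to -1.42.

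Against 569 genes higher and 369 lower in Cd27-only cells, classes from counts as deposited gave 1121 and 803, and at least 2 UMIs 240 and 148 (fewer cells). Clusters, formed from the same counts, gave 2062 and 1681. The fit with no replicate block gave 336 and 146, all 482 of them among the 938, and DESeq2 212 and 86, so 71.1% of its calls were higher against 60.7%. The wider NK class gave 566 lower and doublets kept 233 lower. Without a tag, 403 to 489 were higher and 191 to 297 lower. Of 1156 pairs of a named gene and a setting, 1062 kept direction and side of the threshold, 68 lost the call, 22 gained one and 4 turned direction. Those 4 were Hist1h1b at -1.01 without cells holding Mki67 or Top2a and at -0.13 without the deepest cells, S100a4 at 0.19 with doublets kept, and Ccl4 at 0.050 in the wider NK class. With a minimum of 10 CPM, 7 of the 24 genes would have been named. Depth limits the KATP genes other than Kcnj8, at 3 UMIs or fewer.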

Other observations

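The tests on depth, free RNA, the Ccl3 and Ccl4 cluster, Klrg1 and splits of the samples were chosen after their results or closely related values had been seen; those on doublets, other cell types and nuclear RNA were not.

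Tag 1 differed from the other tags in its NK-like cells. The NK-like cluster led by Ccl4, Cma1, Sgk1, Gzmb, Klrg1 and Ccl3 made up 9.56% of tag 1, 1.88% of tag 2 and 1.29% of tag 3. In all NK-like cells Dusp1 stood at 309 CPM in tag 1 against 94.6 and 90.9 in tags 2 and 3, Fos at 613 against 262 and 192, and Junb at 1852 against 769 and 839. Over 17 immediate early and heat shock genes the median log2 ratio of tag 1 to the mean of the other tags (5 CPM added) was 0.66, with 14 above 0; Dusp2 (-0.27), Hsp90aa1 (-0.04) and Hspa8 (-0.04) were not. With 1 set of cells per tag, these differences have no replicate check.

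A larger share of that cluster is a possible explanation that the values leave open: within clusters 1 to 4 the median ratio ran from 0.25 to 0.60, and without cluster 9 it was 0.57, so a part lay outside that cluster, but the lowest value missed the bound of 0.3 set for excluding it. A difference that reached other cell types of the tag may also contribute. The median was 0.45 in conventional dendritic cell-like, 0.82 in ILC1-like but 0.19 in B cell-like cells, between the bounds of 0.1 and 0.3. It was 1.25 in erythroid-like and 0.076 in T cell-like cells, the latter below both bounds but from 40 cells of tag 1. Erythroid-like cells of tag 1 were shallower, with a median of 12982 UMIs against 23995.5 in the other tags. The tag, its animal and its handling cannot be told apart in 1 library, and no biological explanation was tested.

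The lower Kcnj8 in Cd27-only cells was set against 3 technical explanations. At 2500 UMIs per cell, Itgam-only cells held 2.39 times as many Kcnj8 UMIs (1.84 to 3.15, counting interval, and 1.56 to 3.70 over tags). This argues against depth as the whole cause of the 2.97-fold difference in the main fit. Without the 1781 cells nearest to several-tag barcodes the log2 fold was -1.63 (SE 0.17, edgeR adjusted p = 2.3e-08). Over all alternatives, by edgeR or DESeq2, adjusted p ran from 4.0e-26 to 3.7e-04. The difference thus did not depend on the cells most like several-tag barcodes. Whether the removed cells were the doublets of 1 tag was not shown, so doublets stay open as a part of the cause. B cell-like cells reached at most 12.3% of the Itgam-only level in a tag, which argues against free RNA as the source of the Itgam-only level. They stood at 4.04, 8.13 and 1.97 CPM in tags 1, 2 and 3, against 22.6, 17.6 and 32.1 in Cd27-only cells. A part of that lower value may therefore be free RNA. That Kcnj8 rises with NK maturation is a hypothesis from the same data, and the classes are defined by transcripts, not by protein or time.

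The large number of Kcnq5 UMIs may come in part from nuclear RNA with introns, since the gene is long. Cluster 5, an unnamed cluster with a median of 1394 UMIs, had 1.77 times the Malat1 of NK-like cells and 4.04% ribosomal protein UMIs against 18.2%. Kcnq5 was 2.31 times higher there than in NK-like cells (1.84 to 2.75 over tags), while Kcnj8 stood at 0.236 times (0.135 to 0.385). At 12.6 CPM (7.18 to 20.4), Kcnj8 in cluster 5 was near its level in NK-like cluster 1, at 13.3. Cluster 5 also had 2.96% mitochondrial UMIs against 1.37%. A higher level of Kcnq5 messenger RNA in those cells stays open, and reads, which could place UMIs in introns or exons, were not used here.

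Kcnj8 was also compared within one class. Among Itgam-only cells, those without a Klrg1 UMI had less Kcnj8 than those with one, at a log2 fold of -1.07 (SE 0.12, edgeR adjusted p = 1.9e-12). Klrg1 was picked because both genes already stood among the 10 leading genes of clusters 2 and 4, so the value describes these cells and tests no relation between the genes.

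For the comparison of Cd27-only with Itgam-only cells, the 6 sums can be split in 10 ways into 3 and 3. The real split, the 1 with a result as large, called 938 genes and the highest other called 1; 10 splits are too few for a share under 0.05. Since sums of a tag are paired, the splits closest to the real one are those that part every tag: the other 3 of this kind called 0, 0 and 1 genes, and the 6 that keep a tag together called 0 each.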
